A study of Mus musculus with 9 samples.

How the data were processed

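Total RNA from 9 samples of J1 mouse embryonic stem cells, a line of the 129S4/SvJae strain grown without feeder cells on gelatin, was measured on Agilent arrays with a single dye, Cy3. The labels put 3 samples in each of 3 groups, treated for 24 h with DMSO (the solvent control), 3 µM CHIR99021 or 1 mM AICAR, in medium with 1000 U/mL of leukaemia inhibitory factor (LIF). The labels number the replicates but do not say whether they came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

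The deposited scanner files give each spot's intensity on a linear scale, and per the file headers they were made with Agilent Feature Extraction 10.7.3.1. The software gives a processed signal, and how it treated the background was not examined here. Feature Extraction 10.7 is also the tool in the submitters' processing notes. The deposited series matrix holds a value per probe that followed the log2 of the processed signal on every array, with correlations of 0.99962 to 0.99998 across probes. Its columns had a median of 5.18 on each of the 9 arrays and an equal 75th percentile of 8.90. How these values were centred is not given in the sources used here, and they served only as an alternative.

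The values analysed were the log2 of the processed signal minus each array's 75th percentile over its 59305 spots that are not controls. Spots marked as outliers by the software, 136 to 192 per array, were left out, and spots of a probe were averaged. Probes were kept when well above background on at least 3 of the 9 arrays, which left 37742 of 55681 probes. Gene names came from the accession of each probe, matched without versions to the RefSeq gene table of assembly GRCm38.p6, which was used for names only. Of the probes, 27235 matched and 28446 did not, and these keep the name in the file. The file headers name the genome build mm9 for features given as chromosome intervals. No positions are given for genes, because the table's assembly differs from that build.

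For each gene the probe with the highest mean over the 9 arrays was tested, which gave 26866 features, 16090 with a gene symbol and 10776 without, among them 3693 chromosome intervals. A missing value on some array remained for 71 features, and 1 tested probe was saturated on some array. Probes for near-identical gene copies, such as those of the Zscan4, Usp17, Pramel and Defa families, may bind transcripts of more than 1 copy, so values of such genes are uncertain as to the copy. Lists and families that hold several such copies may count the same transcripts more than once.

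All 9 arrays were fitted together with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the data.table package of version 1.17.8. Adjusted p-values are Benjamini-Hochberg values of this fit over all 26866 features of a comparison, and a feature is said to have risen or fallen when its adjusted p was under 0.05. Errors of log2 fold changes are standard errors of the fit, with n = 3 arrays per group. Where a gene was not well above background on any array of a group, its change is given as a bound. The bound sets the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the gene's own signal and the lowest signal of any probe well above background. It holds for the processed signal. With normexp the fitted changes of the genes the rule picked often fell short of it. They missed 20 of 21 bounds in CHIR99021 against DMSO, 20 of 21 in AICAR against DMSO and 14 of 15 between the treatments. Normexp was run with an offset of 50, above each array's median processed signal of 40.3 to 45.0. Such an offset draws changes toward 0, most for dim genes, so falling short does not test the bounds.

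The groups, the tests, the alternatives, 39 gene lists and the rule for naming genes were set before the data were examined. The rule took the 8 largest rises and 8 largest falls, as fitted, in each comparison with DMSO and the 5 and 5 between the treatments. These came from genes with a symbol whose groups did not overlap. It added up to 4 called members with the largest change from each list described, 20 genes named whatever their result, and 5 genes each with the largest changes in the same or in opposite directions under both treatments. Some genes this rule picked are not reported here. Lists were tested with camera of limma with a preset correlation of 0.01 between genes, adjusted over the 39 lists. They were tested again with an estimated correlation and with fry, which tests whether a list's genes move on balance 1 way and compares them with no other genes.

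The steps were tested on simulated data of 26866 features with unchanged groups, where 100 features were changed at each of the sizes below. A planted log2 change of 1 was called for 86% of features in CHIR99021 against DMSO, 83% in AICAR against DMSO and 89% in CHIR99021 against AICAR. For a change of 0.5 the shares were 53%, 46% and 50%. False calls numbered 7, 4 and 9. In the data 51.0% to 60.8% of features were called, far more than were planted, so these shares and false calls do not carry over to the data.

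The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling by the median, no filter on dim probes, a filter on all 9 arrays, outlier spots kept, the mean of a gene's probes, each probe on its own, only the groups compared, array weights, eBayes with trend and robust settings, a replicate block, the series matrix values and each array left out in turn. The scanner files used here have no column of mean signal, so normexp was run on the median signal and the median background. Scaling by the array's spike-in control probes (E1A) was added after the data were seen. Their mean log2 signal over the 75th percentile was 3.772, 3.997 and 3.721 on the AICAR arrays. On the DMSO arrays it was 3.896 to 3.991, so it differed within AICAR as well as between groups. This scaling lowered the calls for CHIR99021 against DMSO from 13696 to 9341. A call lost with it may therefore reflect added spread between arrays, which was not tested. The number of arrays limits the precision of all values.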

Results

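The study measured which genes respond to CHIR99021, an inhibitor of the kinase GSK3 that activates Wnt/beta-catenin signalling, and to AICAR, a nucleoside that cells convert to an AMP analogue that activates the kinase AMPK. J1 mouse embryonic stem cells kept in LIF were treated for 24 h with DMSO, 3 µM CHIR99021 or 1 mM AICAR, with 3 arrays per group. On the 9 arrays, 62.8% to 67.2% of spots were well above background, and the 75th percentile of the processed signal lay between 567 and 617. Arrays of a group correlated across features at 0.995 to 0.997, and arrays of different groups at 0.973 to 0.983. The median SD between arrays of a group was 0.07 on the log2 scale in DMSO, 0.09 in CHIR99021 and 0.11 in AICAR. Each group lay on a slide of its own, scanned on its own, so slide and group cannot be told apart in any comparison.

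CHIR99021 was compared with DMSO to find the genes that respond to GSK3 inhibition. The largest rises included genes that Wnt/beta-catenin signalling is known to induce. T (Brachyury), a T-box factor of the primitive streak, was higher by 8.27 ± 0.23 on the log2 scale, and was well above background on 2 of the 3 DMSO arrays. Sp5, a zinc finger gene induced by Wnt signals, was higher by 7.94 ± 0.07, and the homeobox genes Cdx2 and Cdx1 by 7.27 ± 0.32 and 6.51 ± 0.05. Dkk4, a secreted Wnt antagonist, was higher by 7.93 ± 0.26 and was well above background on 1 of the 3 DMSO arrays. Otx2, a homeobox gene of the primed epiblast, fell, with a log2 fold change of -5.17 ± 0.07.

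Other genes with the largest rises were not well above background in DMSO. Btla, a receptor of lymphocytes, was at least 55.2-fold higher, Dmgdh, a mitochondrial dimethylglycine dehydrogenase, at least 52.8-fold, Cnga4, a cyclic nucleotide-gated channel subunit, at least 24.4-fold, and the homeobox gene Evx1 at least 24.0-fold. Without DMSO replicate 3 the fitted log2 fold change of Dmgdh moved from 7.20 to 7.81. The other large falls ended below background in CHIR99021. Pax6, a neural and eye homeobox gene, was at least 13.6-fold lower, Trem2, a receptor of myeloid cells, at least 8.30-fold, Duxbl1, a double homeobox gene, at least 7.38-fold, and the collagen gene Col8a2 at least 6.80-fold. Tnfsf11, which encodes the cytokine RANKL, was at least 6.67-fold lower, Shisa3 at least 3.68-fold, and the dicarboxylate transporter Slc13a3 at least 3.49-fold. These bounds hold for the processed signal. With normexp the fitted log2 fold changes fell short of them, at 3.05 for Btla, 2.98 for Dmgdh, 2.41 for Cnga4, 2.11 for Evx1, -1.52 for Pax6, -1.08 for Trem2, -0.998 for Duxbl1, -1.05 for Col8a2, -1.09 for Tnfsf11, -0.51 for Shisa3 and -0.61 for Slc13a3.

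Of the Wnt/beta-catenin target genes, 18 of 26 tested members rose and 5 fell with CHIR99021 (camera adjusted p = 0.000549, and adjusted p = 0.0528 with an estimated correlation). Myc was among those that fell, at -0.59 ± 0.08, and Lef1 did not pass the test, at -0.14 ± 0.06 with a limma adjusted p of 0.0780. Of 13 Wnt pathway repressors that Wnt signals induce as negative feedback, 10 rose and 2 fell (camera adjusted p = 0.00211, and adjusted p = 0.0671 with an estimated correlation). Axin2 was higher by 5.12 ± 0.09, Rnf43 by 2.78 ± 0.06 and Dkk1 by 2.45 ± 0.25, the last well above background on 1 DMSO array. The 2 probes of Axin2 gave log2 fold changes of 3.83 and 5.12.

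Genes of body axis patterning and the primitive streak rose as well. Of 24 Hox cluster genes, 19 rose and 0 fell (camera adjusted p = 5.04e-07, and adjusted p = 0.0190 with an estimated correlation). Their median log2 fold change was 1.65, or 1.62 with members below background at their bounds. Hoxd4 was at least 9.09-fold higher, Hoxd9 at least 4.06-fold and Hoxc9 at least 3.76-fold, and Hoxb8, well above background on 2 DMSO arrays, was higher by 3.64 ± 0.33. Of 18 primitive streak and mesendoderm genes, 13 rose and 2 fell (camera adjusted p = 0.00233, and adjusted p = 0.0541 with an estimated correlation). Besides T and Evx1, Wnt5b rose by 2.72 ± 0.07 and Gsc by 2.00 ± 0.20. This list's call was lost with the filter on all 9 arrays.

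Genes of the naive and primed pluripotent states moved in opposite directions with CHIR99021. Of 22 naive pluripotency genes, 15 rose and 4 fell (camera adjusted p = 0.0117, and adjusted p = 0.218 with an estimated correlation). Tfcp2l1, a transcription factor of the naive state, was higher by 2.59 ± 0.05, Gbx2 by 1.28 ± 0.06, Prdm14 by 1.16 ± 0.07, Tbx3 by 1.13 ± 0.05, Klf4 by 1.06 ± 0.04, Esrrb by 0.73 ± 0.05 and Klf2 by 0.54 ± 0.06. Nanog did not pass, at 0.12 ± 0.10 with a limma adjusted p of 0.368. Of 16 primed epiblast genes, 13 fell and 1 rose (camera adjusted p = 8.66e-10, and adjusted p = 0.0148 with an estimated correlation). Besides Otx2, Pim2 had a log2 fold change of -2.28 ± 0.09, Car14 of -2.19 ± 0.08 and the de novo DNA methyltransferase gene Dnmt3b of -0.95 ± 0.05, while Fgf5 was at least 2.27-fold lower.

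Of 15 core pluripotency genes, 10 fell and 1 rose (camera adjusted p = 0.000549, and adjusted p = 0.0528 with an estimated correlation). The members with the largest falls were Foxd3, a forkhead repressor, at -1.38 ± 0.08, Utf1, a chromatin-bound protein, at -1.22 ± 0.06, L1td1, an RNA-binding protein, at -0.98 ± 0.05, and Dppa4 at -0.61 ± 0.05. Pou5f1, which encodes Oct4, did not pass, at 0.18 ± 0.17 with a limma adjusted p of 0.419. Sox2 was the member that rose, by 0.26 ± 0.06 with a limma adjusted p of 0.00728, a call that was lost with spike-in scaling, where the adjusted p was 0.0920.

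Some lineage and signalling lists fell. Of 16 Nodal/TGF-beta and BMP target genes, 10 fell and 4 rose (camera adjusted p = 0.00197, and adjusted p = 0.0541 with an estimated correlation). Lefty1, a Nodal antagonist, was at -3.05 ± 0.08, while Id3 and Id4, which BMP signals induce, rose by 1.46 ± 0.06 and 1.41 ± 0.13. Of 15 neural ectoderm genes, 9 fell and 4 rose (camera adjusted p = 0.0197, and adjusted p = 0.288 with an estimated correlation), with Neurod1 at -1.99 ± 0.21 and Pax3 higher by 1.57 ± 0.06. This call was lost with the filter on all 9 arrays, with the mean of a gene's probes and with each probe on its own. Of 24 extracellular matrix and adhesion genes, 15 fell and 5 rose (camera adjusted p = 0.00211, and adjusted p = 0.0541 with an estimated correlation), among them Col18a1 at -1.25 ± 0.05 and Itga3 at -1.20 ± 0.08, while Cdh2, N-cadherin, rose by 1.22 ± 0.11.

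Several lists of metabolism, cell cycle and epigenetic regulation also fell. Of 32 one-carbon, serine and amino acid genes, 21 fell and 5 rose (camera adjusted p = 0.000364, and adjusted p = 0.0541 with an estimated correlation), with Chac1 at -1.48 ± 0.07, Cth at -1.36 ± 0.06 and asparagine synthetase (Asns) higher by 0.98 ± 0.05. Of 25 mitotic cell cycle genes, 16 fell and 2 rose (camera adjusted p = 0.000775, and adjusted p = 0.218 with an estimated correlation). These falls were small, as for Hmmr at -0.55 ± 0.11 and Nusap1 at -0.54 ± 0.05, whereas the mitotic kinase gene Aurkb rose by 1.72 ± 0.08. Of 17 hypoxia-responsive genes, 8 fell and 1 rose (camera adjusted p = 0.00436, and adjusted p = 0.138 with an estimated correlation), with Adm at -1.30 ± 0.05 and Car9 at -1.23 ± 0.07.

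Of 20 genes of DNA methylation and TET enzymes, 10 fell and 3 rose with CHIR99021 (camera adjusted p = 0.00508, and adjusted p = 0.0957 with an estimated correlation). Gadd45g was at -2.44 ± 0.06 and Dnmt3l, a cofactor of the de novo methyltransferases, at -2.27 ± 0.07. Of 23 germline genes that DNA methylation silences, 12 fell and 3 rose (camera adjusted p = 0.00133, and adjusted p = 0.218 with an estimated correlation), with Zcwpw1 at -1.49 ± 0.06 and Stra8 at -1.22 ± 0.13. Of 29 imprinted genes, 15 fell and 4 rose (camera adjusted p = 0.00177, and adjusted p = 0.110 with an estimated correlation). Cdkn1c, a cell cycle inhibitor, was at -2.59 ± 0.07, while Plagl1 rose by 4.06 ± 0.12 at its brightest probe and its probes ranged from 0.13 to 4.18. Of 13 interferon-stimulated genes, 6 fell and 2 rose (camera adjusted p = 0.0191, and adjusted p = 0.108 with an estimated correlation), with Gbp2 at -2.88 ± 0.11 and Cxcl10 at least 5.38-fold lower. This last list's call was lost with the filter on all 9 arrays and with each probe on its own.

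Of the remaining genes named in advance, Cdkn1a, which encodes the cell cycle inhibitor p21, was higher with CHIR99021 by 1.91 ± 0.11 at its brightest probe, and its probes ranged from 0.39 to 1.91. Gata6, a factor of the primitive endoderm, was higher by 0.29 ± 0.07 with a limma adjusted p of 0.0116, a call lost with normexp (adjusted p = 0.143) and with spike-in scaling (adjusted p = 0.192).

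In all, 13696 of 26866 features passed the limma test between CHIR99021 and DMSO, 8180 higher and 5516 lower, and 2093 of them differed at least 2-fold, 1033 higher and 1060 lower. With normexp 722 differed at least 2-fold, 408 higher and 314 lower. Of the called features, 61.8% differed by less than 1.5-fold. With spike-in scaling 4551 features were higher and 4790 lower, so the balance between rises and falls rests on the scaling. By camera 17 of 39 lists passed, 5 up and 12 down, and with an estimated correlation 2 did, the Hox and primed epiblast lists. Adjusted over the list alone, the counts of these 17 lists were the same except that 6 Wnt/beta-catenin targets, 15 primed epiblast, 11 Nodal/TGF-beta and BMP and 17 mitotic genes fell, and 20 Hox, 6 amino acid and 4 DNA methylation genes rose. Markers of fibroblasts, the usual feeder cells, did not pass as a list, with 2 of 13 higher and 5 lower (camera adjusted p = 0.209). With normexp the log2 fold change of T was 5.67.

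**Figure D1:**
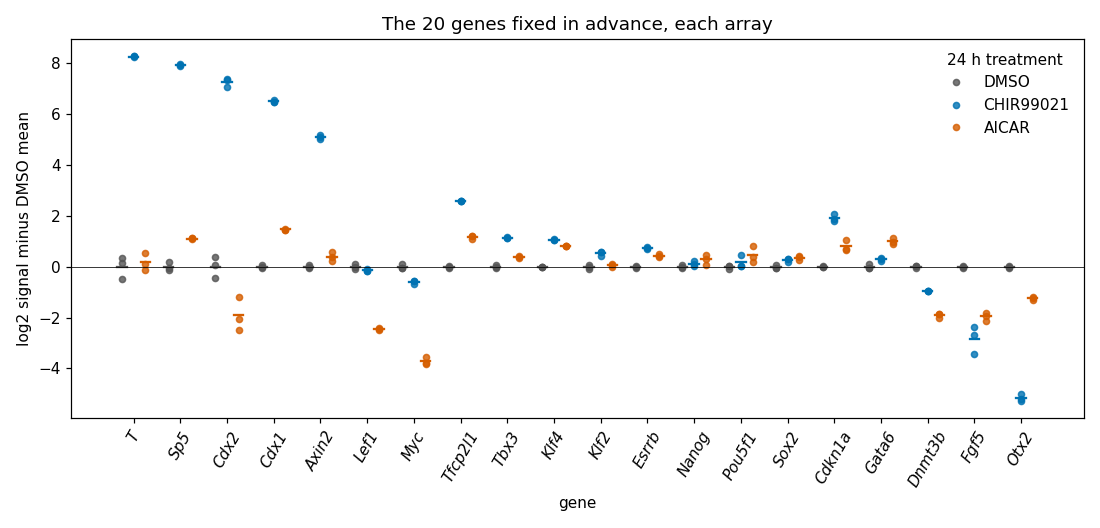
Log2 signal of the 20 genes named in advance on each of the 9 arrays, minus the gene's mean over the 3 DMSO arrays. Points are arrays, short bars are group means, and colours are the treatments. T, Sp5, Cdx2, Cdx1 and Axin2 lay highest in CHIR99021, with T at 8.27, and Myc fell by 3.72 in AICAR. Points of Cdx2 in AICAR and of Fgf5 in both treatments were not well above background.

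AICAR was compared with DMSO to find the genes that respond to this activator of AMPK. Otop2, a proton channel gene, was at least 16-fold higher, and Mal, a membrane protein of myelin and lymphocytes, was higher by 3.94 ± 0.13. The other largest rises began below background in DMSO. Dner was at least 11.2-fold higher, Rnase2a at least 6.89-fold, Bhmt2, a methyltransferase of homocysteine, at least 4.84-fold, Rnf186 at least 4.42-fold, Nrl at least 4.25-fold and Serpinb1c at least 2.70-fold. The Wilms tumour gene Wt1 fell, with a log2 fold change of -4.99 ± 0.08, as did Vrtn at -4.61 ± 0.07, Zscan4f at -3.87 ± 0.07 and Zscan4a at -3.76 ± 0.09. Pramel16 was at least 8.78-fold lower, Usp17lb at least 8.11-fold, Platr8, a long non-coding RNA, at least 7.34-fold and Hoxb1 at least 6.54-fold. With normexp the fitted log2 fold changes fell short of these bounds, at 1.57 for Otop2, 1.21 for Dner, 0.90 for Rnase2a, 0.64 for Bhmt2, 0.78 for Rnf186, 0.69 for Nrl, 0.54 for Serpinb1c, -1.21 for Pramel16, -0.91 for Usp17lb and Platr8 and -0.92 for Hoxb1.

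Genes that build ribosomes fell with AICAR. Of 27 ribosome biogenesis and nucleolar genes, 25 fell and 1 rose, with a median of -0.67 (camera adjusted p = 9.36e-08, and adjusted p = 0.0546 with an estimated correlation). Gnl3, nucleostemin, was at -1.05 ± 0.08, nucleolin (Ncl) at -0.89 ± 0.14, and Pes1 at -1.98 ± 0.06 at its brightest probe, its probes ranging from -1.98 to -0.71. Of 27 ribosomal protein genes, 14 fell and 0 rose, with a median of -0.14 (camera adjusted p = 0.00688, and adjusted p = 0.509 with an estimated correlation). Rpl19, at -0.30 ± 0.05, had the largest fall, which was lost with spike-in scaling (limma adjusted p = 0.175). The ribosomal protein list lost its call with quantile normalization, the series matrix values and spike-in scaling, and its median reached 0.03 among the scalings. Myc, a transcription factor that drives ribosome biogenesis, was at -3.72 ± 0.08.

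Genes of lipid and glucose metabolism rose with AICAR. Of 25 cholesterol synthesis and SREBP2 genes, 20 rose and 1 fell (camera adjusted p = 0.000166, and adjusted p = 0.237 with an estimated correlation), with Stard4 higher by 1.33 ± 0.07, Cyp51 by 1.04 ± 0.04 and Pmvk by 0.90 ± 0.08. Of 17 fatty acid synthesis genes, 12 rose and 2 fell (camera adjusted p = 0.0102, and adjusted p = 0.135 with an estimated correlation), with Thrsp higher by 2.31 ± 0.05 and the desaturase gene Scd1 by 1.35 ± 0.09. Of 25 fatty acid oxidation genes, 17 rose and 3 fell (camera adjusted p = 0.00462, and adjusted p = 0.135 with an estimated correlation). Pdk4, which restrains pyruvate oxidation, was higher by 1.64 ± 0.08, and Cpt1a, which brings fatty acids into mitochondria, by 0.77 ± 0.06.

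Of 21 glycolysis genes, 14 rose and 2 fell with AICAR (camera adjusted p = 0.0176, and adjusted p = 0.356 with an estimated correlation), with Aldoc higher by 1.59 ± 0.06 and Eno3 at -1.35 ± 0.05. Of 17 hypoxia-responsive genes, 14 rose and 1 fell (camera adjusted p = 0.000364, and adjusted p = 0.135 with an estimated correlation), with the angiogenic factor gene Vegfa higher by 1.84 ± 0.04, Ddit4, an inhibitor of mTORC1, by 1.78 ± 0.16 and Ndrg1 by 1.69 ± 0.07. Of 25 purine synthesis and salvage genes, 16 fell and 4 rose (camera adjusted p = 0.0322, and adjusted p = 0.221 with an estimated correlation). Prps2 was at -0.82 ± 0.10 and Nt5e at -0.74 ± 0.08, while Adssl1 rose by 1.58 ± 0.07. The purine list's call was lost with quantile normalization, the series matrix values and spike-in scaling.

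Primed epiblast and core pluripotency genes fell with AICAR. Of 16 primed epiblast genes, 14 fell and 2 rose (camera adjusted p = 2.46e-06, and adjusted p = 0.0517 with an estimated correlation). Wnt8a was at -3.57 ± 0.07, Lef1 at -2.45 ± 0.06, Zic2 at -2.15 ± 0.07, Dnmt3b at -1.91 ± 0.05 and Otx2 at -1.25 ± 0.07, while Fgf5 was at least 2.71-fold lower. Of 15 core pluripotency genes, 11 fell and 3 rose (camera adjusted p = 0.00276, and adjusted p = 0.115 with an estimated correlation), with Foxd3 at -1.74 ± 0.08, L1td1 at -1.41 ± 0.05 and Lin28a, which blocks maturation of let-7 microRNAs, at -1.34 ± 0.07. Pou5f1 did not pass, at 0.46 ± 0.17 with a limma adjusted p of 0.0506, and Sox2 rose by 0.36 ± 0.06. The 22 naive pluripotency genes did not pass as a list, with 9 higher and 7 lower (camera adjusted p = 0.878). Among them Tfcp2l1 was higher by 1.16 ± 0.05, Klf4 by 0.83 ± 0.04, Esrrb by 0.44 ± 0.05 and Tbx3 by 0.37 ± 0.05, and Klf2 was at 0.05 ± 0.06 with a limma adjusted p of 0.513.

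Nanog was higher with AICAR by 0.29 ± 0.10 with a limma adjusted p of 0.0413, and over the alternatives its adjusted p ranged from 0.00652 to 0.154. The call of Nanog was lost without DMSO replicate 1 (0.0518), 2 (0.113) or 3 (0.0966), without CHIR99021 replicate 2 (0.0505) or 3 (0.0575), and without AICAR replicate 1 (0.113) or 2 (0.0911), where the values are adjusted p of limma. It was also lost with normexp, scaling by the median, no filter and only the groups compared.

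Genes of the 2-cell-like state, which marks a rare state of embryonic stem cells, fell with AICAR in 8 of 12 tested cases and rose in 2 (camera adjusted p = 0.00462, and adjusted p = 0.119 with an estimated correlation). Their median log2 fold change was -2.08, or -1.68 with members below background at their bounds. Zscan4c was at -3.61 ± 0.12, Gm4340 at -3.20 ± 0.14 and Tcstv1, well above background on 1 AICAR array, at -2.99 ± 0.32. Of 19 ERK-responsive and immediate-early genes, 11 fell and 4 rose (camera adjusted p = 0.0121, and adjusted p = 0.135 with an estimated correlation), with Egr1 at -3.27 ± 0.08, Dusp6 at -2.15 ± 0.06 and Fos higher by 1.76 ± 0.05. Of 20 genes of DNA methylation and TET enzymes, 12 fell and 1 rose (camera adjusted p = 0.0121, and adjusted p = 0.135 with an estimated correlation), with Dnmt3l at -2.67 ± 0.07, while Gadd45b rose by 1.68 ± 0.05. Of 29 imprinted genes, 16 fell and 5 rose (camera adjusted p = 0.0362, and adjusted p = 0.273 with an estimated correlation), with Mirg at -1.66 ± 0.19 and Mest at -1.43 ± 0.05, and this call was lost with scaling by the median.

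Of 13 Wnt pathway repressors, 8 rose and 2 fell with AICAR (camera adjusted p = 0.0476, and adjusted p = 0.221 with an estimated correlation), with Rnf43 higher by 1.37 ± 0.06 and Sfrp5 by 1.14 ± 0.09. This call was lost without DMSO replicate 1, CHIR99021 replicate 2 or AICAR replicate 2, where the camera adjusted p was 0.0652, 0.0508 and 0.0535. It was also lost with quantile normalization, the mean of a gene's probes, only the groups compared, the replicate block, the series matrix values and spike-in scaling. The Wnt/beta-catenin targets did not pass as a list, with 12 of 26 higher and 8 lower (camera adjusted p = 0.601). Cdx1 was higher by 1.47 ± 0.05 and Sp5 by 1.11 ± 0.07, T did not pass at 0.17 ± 0.23 with a limma adjusted p of 0.551, and Cdx2 was at least 1.54-fold lower, a call lost with normexp (adjusted p = 0.174). The probes of Axin2 disagreed, at -0.23 and 0.38, and those of Cdkn1a ranged from -0.12 to 0.80. Gata6 was higher by 1.00 ± 0.07.

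In all, 16252 of 26866 features passed the limma test between AICAR and DMSO, 8310 higher and 7942 lower, and 3305 of them differed at least 2-fold, 1871 higher and 1434 lower. With normexp 1214 differed at least 2-fold, 612 higher and 602 lower, with scaling by the median 1551 were higher and 1701 lower, and with spike-in scaling 2379 and 1151, so the balance rests on the scaling. Of the called features, 55.3% differed by less than 1.5-fold. Scaling by the median gave 6573 higher and 9515 lower, and spike-in scaling, which moved the median of all log2 fold changes by 0.13, gave 8913 higher and 4555 lower. By camera 15 of 39 lists passed, 6 up and 9 down, and with an estimated correlation 0 did, with a lowest adjusted p of 0.0517. By unadjusted p of camera under 0.05 with that correlation 9 lists would pass, and by fry 34 passed. Adjusted over the list alone, the counts of these 15 lists were the same except that 4 core pluripotency, 21 cholesterol and 6 imprinted genes rose, and 2 cholesterol and 3 fatty acid synthesis genes fell. Markers of fibroblasts did not pass as a list, with 6 of 13 higher and 4 lower (camera adjusted p = 0.529).

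The treatments were compared with each other to test the difference between their effects. Cdx2 was at least 238-fold higher in CHIR99021 than in AICAR, Btla at least 53.8-fold, T by 8.10 ± 0.23 on the log2 scale, Dkk4 by 7.69 ± 0.26 with 1 AICAR array well above background, and Sp5 by 6.83 ± 0.07. Vstm2l was lower in CHIR99021, at -4.42 ± 0.08, as was Tmem235 at -4.15 ± 0.10, while Mall was at least 17.2-fold lower, Lrtm2 at least 6.33-fold and the phosphatase gene Ptpre at least 5.59-fold. With normexp the fitted log2 fold changes fell short of these bounds, at 5.18 for Cdx2, 3.07 for Btla, -1.78 for Mall, -1.003 for Lrtm2 and -0.81 for Ptpre. Of 24 Hox cluster genes, 22 were higher in CHIR99021 and 0 lower (camera adjusted p = 3.85e-07, and adjusted p = 0.0366 with an estimated correlation). Hoxb8 was at least 15-fold higher, Hoxb1 at least 9.37-fold and Hoxb3 at least 8.19-fold, and Hoxb2 was higher by 3.81 ± 0.05. Of 26 Wnt/beta-catenin targets, 18 were higher and 6 lower (camera adjusted p = 0.00149, and adjusted p = 0.0637 with an estimated correlation), with Axin2 higher by 4.73 ± 0.09, Cdx1 by 5.04 ± 0.05, Myc by 3.13 ± 0.08 and Lef1 by 2.31 ± 0.06.

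Ribosome and 2-cell-like genes were higher in CHIR99021 than in AICAR. Of 27 ribosome biogenesis and nucleolar genes, 26 were higher and 0 lower (camera adjusted p = 3.85e-07, and adjusted p = 0.0616 with an estimated correlation), with Gnl3 higher by 1.07 ± 0.08 and Nop56 by 0.99 ± 0.05. Of 27 ribosomal protein genes, 18 were higher and 0 lower (camera adjusted p = 0.0187, and adjusted p = 0.593 with an estimated correlation), and 20 were higher adjusted over the list alone, the only of the 10 called lists where that count differed. The ribosomal protein list's call was lost without CHIR99021 replicate 2, where the camera adjusted p was 0.0554, and with spike-in scaling. With quantile normalization (adjusted p = 0.644) and the series matrix values (adjusted p = 0.709) it was also lost and its direction reversed. The median log2 fold change of all features went from -0.10 in the lowest decile of signal to 0.22 in the highest. That of the ribosomal protein genes, 0.18, was no higher than that of the brightest features, and lists matched on signal were not drawn for this comparison. Of 12 genes of the 2-cell-like state, 11 were higher and 1 lower (camera adjusted p = 0.00367, and adjusted p = 0.0941 with an estimated correlation), with Zscan4f higher by 2.95 ± 0.07.

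Some lists of metabolism were lower in CHIR99021 than in AICAR. Of 17 hypoxia-responsive genes, 14 were lower and 1 higher (camera adjusted p = 3.85e-07, and adjusted p = 0.0616 with an estimated correlation), with Vegfa at -2.14 ± 0.04 and Ndrg1 at -2.11 ± 0.07. Of 25 cholesterol synthesis and SREBP2 genes, 18 were lower and 2 higher (camera adjusted p = 6.29e-06, and adjusted p = 0.267 with an estimated correlation), with Dhcr7 at -0.97 ± 0.08. Of 25 fatty acid oxidation genes, 14 were lower and 3 higher (camera adjusted p = 0.000647, and adjusted p = 0.0983 with an estimated correlation), with Pdk4 at -1.22 ± 0.08. Of 21 glycolysis genes, 14 were lower and 2 higher (camera adjusted p = 0.000711, and adjusted p = 0.286 with an estimated correlation), with Pfkl at -1.46 ± 0.07. Of 23 germline genes that DNA methylation silences, 15 were lower and 6 higher (camera adjusted p = 0.0224, and adjusted p = 0.336 with an estimated correlation), with Dpep3 at -1.32 ± 0.17, and this call was lost with spike-in scaling.

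Among pluripotency genes, Tfcp2l1 was higher in CHIR99021 by 1.42 ± 0.05, Tbx3 by 0.76 ± 0.05 and Dnmt3b by 0.96 ± 0.05, and Otx2 was lower, at -3.92 ± 0.07. The differences of Klf2, Esrrb and Klf4, at 0.49 ± 0.06, 0.29 ± 0.05 and 0.23 ± 0.04, were lost with spike-in scaling, where the limma adjusted p was 0.0713, 0.446 and 0.737. Those of Esrrb and Klf4 were also lost with quantile normalization and the series matrix values. Nanog, Pou5f1 and Sox2 did not pass, at -0.17 ± 0.10, -0.28 ± 0.17 and -0.10 ± 0.06. Gata6 was lower in CHIR99021, at -0.71 ± 0.07, and Cdkn1a higher, by 1.11 ± 0.11. Fgf5 was below background in both groups.

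In all, 16328 features passed the limma test between CHIR99021 and AICAR, 9722 higher in CHIR99021 and 6606 lower, and 3645 differed at least 2-fold, 1413 higher and 2232 lower. Spike-in scaling moved the median of all log2 fold changes by -0.19 and gave 4252 higher and 7823 lower. By camera 10 of 39 lists passed, 5 up and 5 down, and with an estimated correlation 1 did, the Hox list.

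**Figure D2:**
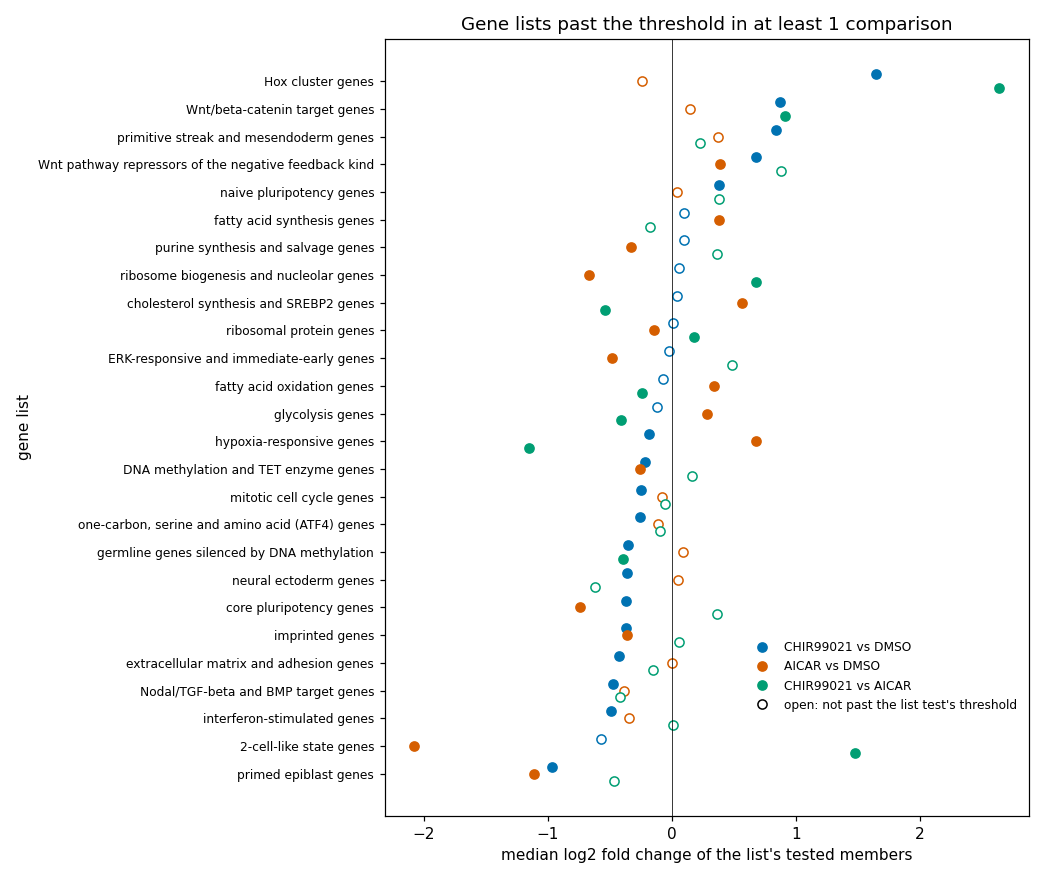
Median log2 fold change of the tested members of each gene list that passed the camera test in at least 1 of the 3 comparisons, with fitted values also for members below background. Filled points are lists past the threshold and open points are not. The Hox list had the highest median in CHIR99021 against DMSO, 1.65, and the 2-cell-like list the lowest in AICAR against DMSO, -2.08. The ribosomal protein medians and several open points near 0 changed sign among the scalings.

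The genes called in both comparisons with DMSO were counted to set the responses side by side. Bhmt2 rose with both, at least 32.4-fold with CHIR99021 and at least 4.84-fold with AICAR, as did Serpinb1c, at least 2.05-fold and at least 2.70-fold. Wt1 fell with both, at -3.63 ± 0.08 and -4.99 ± 0.08, and Tnfsf11 was at least 6.67-fold and at least 7.84-fold lower. Duxbl1 was at least 7.38-fold lower with CHIR99021 and at -3.50 ± 0.47 with AICAR, where 1 array was well above background. Other genes went opposite ways. Cdx2 rose with CHIR99021 and was at least 1.54-fold lower with AICAR, and Vstm2l was at -1.93 ± 0.08 with CHIR99021 and higher by 2.49 ± 0.08 with AICAR.

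Ptpre was at least 1.29-fold lower with CHIR99021 and higher with AICAR by 2.11 ± 0.28, and was well above background on 2 DMSO arrays. Its fall with CHIR99021 was lost with normexp, where the limma adjusted p was 0.377. Dkk1 rose with CHIR99021 by 2.45 ± 0.25 and was at least 1.10-fold lower with AICAR, where its call was lost with normexp (limma adjusted p = 0.0862).

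Both treatments changed 6791 features in the same direction, 4113 up and 2678 down, and 2701 in opposite directions. Scaling by the median gave 2902 up and 3455 down, so the balance between shared rises and falls rests on the scaling. Of those in opposite directions, 1285 rose with CHIR99021 and fell with AICAR. Independent lists of these sizes would share 2530 features up and 1631 down, and 4124 in opposite directions. In 100 simulations of noise without effect, groups set against the same simulated controls shared at most 1 feature. Without effects few features can be called, so this count was low in advance and gives no baseline for the 6791. Of the features changed at least 2-fold in both, 697 went the same way and 126 opposite ways, where independent lists would give 128.5 and 129.0. The log2 fold changes correlated across features at r = 0.351, where features are not independent replicates. Shared controls alone gave a mean r of 0.503 in the simulations, with a range of 0.456 to 0.542. Noise without effect gives such an r whatever its size, so it is no baseline for the r of 0.351. The covariance was 0.162 against a simulated 0.0142, a difference of 0.147. The 3 DMSO arrays cannot be split into parts of at least 2, so part of the excess may come from the shared controls.

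**Figure D3:**
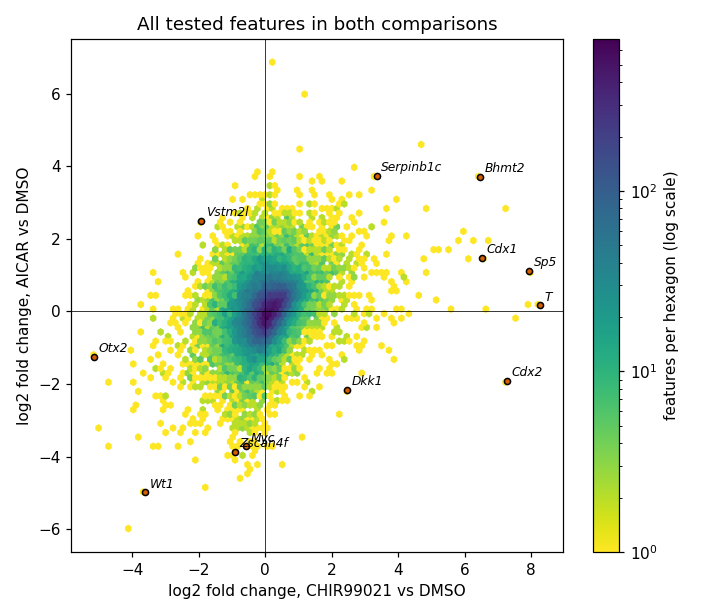
Log2 fold change of the 26866 tested features with CHIR99021 against DMSO on the horizontal axis and with AICAR against DMSO on the vertical axis, both as fitted. Colour gives the number of features per hexagon on a log scale, and orange points mark named genes. Bhmt2, Serpinb1c and Wt1 lay in the quadrants of equal direction, Cdx2, Dkk1 and Vstm2l in those of opposite direction, and r was 0.351.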

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

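Scaling by spike-in probes was chosen after the data were seen. The counts of features called in the 3 comparisons and of features changed the same way by both treatments stayed within 1.5 times under every alternative run, as did the counts of lists under the settings not named here. Over all alternatives, 2715 of 2925 list tests kept direction and side of the threshold, 64 lost the call, 144 gained it and 2 reversed, and for named genes these were 11706, 178, 21 and 3 of 11908. With an estimated correlation camera passed 2 lists for CHIR99021, 0 for AICAR and 1 between the treatments, and fry passed 34 in each. Not every lost list had an estimated correlation above the preset 0.01. For the Wnt/beta-catenin targets with CHIR99021 it was -0.0135, and the unadjusted p of camera still rose from 5.9e-05 to 0.0041. For the primed epiblast list it was -0.0166, and p rose from 2.2e-11 to 0.00038. For the Hox list it was 0.0028, and p rose from 2.6e-08 to 0.00098. These values argue against a higher correlation between genes as the reason for these lists, and what raised p was not tested. Unlike camera, fry compares a list with no other genes.

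With normexp 722 features changed at least 2-fold with CHIR99021 and 1214 with AICAR, 16 lists passed between the treatments and r was 0.364. Without the filter 16 lists passed between the treatments and r was 0.363, with the filter on all 9 arrays r was 0.365 and with each probe on its own 0.360. Leaving out an array gave r from 0.339 to 0.365. The list of ribosomal proteins between the treatments reversed with quantile normalization (adjusted p = 0.644) and with the series matrix values (adjusted p = 0.709), over a range of 0.000422 to 0.709 for all alternatives. The log2 fold change reversed with normexp for Afp with CHIR99021 (0.0143) and Fgf5 between the treatments (0.0455), and with the series matrix values for Atp5o between the treatments (-0.0049). The normexp offset draws changes toward 0, most for dim features. How far it accounts for the normexp values was not tested, nor were causes of the other differences.

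Samples of equal replicate number deviated together with r from -0.055 to 0.088 across features, and 0 of 9 pairs exceeded 0.1, so the numbers were not taken as pairing. The replicate block gave 12711 calls for CHIR99021, 15460 for AICAR and 15682 between the treatments, and 2080 and 3286 at least 2-fold. It gave 6176 in the same direction with both and 17, 14 and 10 lists. A slide block was not run, because each slide held a single group. Signal over background limits what could be measured, since 62.8% to 67.2% of spots per array were well above it.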

Other observations

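The gene families, chromosome intervals and disagreeing probes here were chosen after the values were seen, as were the tests of slides holding several groups, of the DMSO slide, of the shared DMSO arrays and of naive genes.

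Families of genes that share the start of their symbol were tested as lists. Of 265 families tested with camera, 32 passed with AICAR, 7 up and 25 down, 2 with CHIR99021 and 25 between the treatments, and with an estimated correlation 0 passed in each, where 32, 15 and 31 had an unadjusted p of camera under 0.05. With AICAR 16 of 19 kallikrein (Klk) genes rose and 1 fell (camera adjusted p = 0.000552, and adjusted p = 0.404 with an estimated correlation), as did 18 of 27 keratin (Krt) genes with 1 lower (0.00308 and 0.337) and 10 of 11 T-box (Tbx) genes (0.0231 and 0.404). Translation initiation (Eif) genes fell in 37 of 55 cases and rose in 4 (0.000102 and 0.162), splicing factor (Srsf) genes in 9 of 10 with 1 higher (0.00974 and 0.404), chaperonin (Cct) genes in 8 of 8 (0.0186 and 0.311) and mitochondrial import (Timm) genes in 13 of 15 (0.0016 and 0.313). Defensin (Defa) genes fell in 8 of 12 cases with 1 higher (0.00103 and 0.306), and Hoxb genes in 9 of 10 (0.00172 and 0.326). Probes of Defa copies may bind the same transcripts, so the 12 may not be separate readings, though the tests treat them so. The whole Hox list, set in advance, did not pass with AICAR, with 7 of 24 higher and 12 lower (camera adjusted p = 0.263) and a median of -0.24, or -0.13 with members below background at their bounds. With CHIR99021 17 of 33 collagen (Col) genes fell and 2 rose (0.0225 and 0.691), and 8 of 12 Serpinb genes rose (0.0225 and 0.691). The medians of these families kept their sign under quantile, median and spike-in scaling. Of 10000 random lists matched on signal, 8.0% had a median as low as the Cct genes with AICAR and 5.4% as low as the Timm genes, so the fall of bright genes with AICAR may account for these 2. For the other families, in the comparison named for each, at most 0.73% were as far out. Serpinb also passed camera with AICAR, at a median log2 fold change of 0.42, where 2.07% were as far out. The shares set the families against signal only. As the families were picked from 265 after their values were seen, low shares were likely in advance and are no further support.

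Features named as chromosome intervals of build mm9 also changed. Of 3693 tested, 1378 rose and 442 fell with CHIR99021, and 1129 rose and 703 fell with AICAR. These are 49.3% and 49.6% of the intervals, against 51.0% and 60.5% of all features, so intervals were not called more often. For all features the balance of rises and falls rested on the scaling, and that of intervals under other scalings is not given here. At least 2-fold, 110 rose and 70 fell with CHIR99021, while with AICAR 167 rose and 220 fell. Changes of intervals well above background on an array of both groups, as fitted, reached 2.84 ± 0.22 with CHIR99021 at chromosome 19, 29969050 to 29980675 (limma adjusted p = 2.88e-05), and -2.18 ± 0.26 at chromosome 18, 75513062 to 75523889. With AICAR they reached 3.40 ± 0.22 at chromosome 8, 87513394 to 87514107, and -4.10 ± 0.15 at chromosome 13, 31736054 to 31781679. Intervals below background in a group have only bounds and were not ranked.

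Probes of a gene could also disagree. Of 4198 genes with several kept probes, 1 had probes called at least 2-fold in opposite directions with CHIR99021, Prlr, at 1.37 ± 0.10 and -1.19 ± 0.20. With AICAR 4 did, Foxp1, Fsd1l, Btg1 and Adam32. The bright probes of Foxp1 were at -1.27 ± 0.06 and -1.35 ± 0.07 and a dim probe at 1.11 ± 0.17.

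Features called against DMSO numbered 13696 with CHIR99021 and 16252 with AICAR, while each group had a slide of its own. A difference between slides that acts probe by probe would leave a gene's second probe unrelated to its brightest. The second-brightest probe was called in the same direction for 84.2% of features changed at least 2-fold with AICAR (exact 95% interval 81.3% to 86.9%, 692 features), above the bound of 80% set for this test, against 29.5% for random pairs, which argues against that explanation there. With CHIR99021 the share was 83.2% (79.1% to 86.8%, 387 features, random pairs 19.12%). For features called below 1.5-fold the sign was shared in 78.6% (77.0% to 80.2%) with CHIR99021 and 80.6% (79.0% to 82.1%) with AICAR, against 51.1% and 50.7%. These intervals reach below the bound, so by the interval the explanation is left open in part. The bound was set for the share itself, which 83.2% and 80.6% exceed and 78.6% does not. Each share lay well above its random pairs, which argues against wholly unrelated probes. As 0 slides held more than 1 group, a difference between slides of another kind was not tested. The labels name no batch of culture, RNA extraction or labelling, and none was tested.

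More features changed in the same direction with both treatments than in opposite directions, 6791 against 2701. Chance values of the shared DMSO arrays would give a covariance within the simulated range, and the observed covariance was 9.83 times the highest of 100 simulations, which argues against chance as the whole cause. Other measures did not exceed the simulations. The sign was equal for 62.5% of features against 66.7% simulated, and r was 0.351 against a lowest simulated 0.456. A shift of the DMSO samples may also give more features in the same direction. It cannot be told apart from a shared response, because all DMSO arrays lay on 1 slide. A candidate explanation was that both treatments raise naive and lower primed genes. It asks the naive list to rise in both comparisons, which was not met with AICAR. There 9 naive genes were higher and 7 lower, with a median log2 fold change of 0.042 (camera adjusted p = 0.878). The list did not fall past the threshold either, the outcome set against the explanation, so the naive genes did not settle it.

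Ribosome genes fell with AICAR, while the median log2 fold change of all features went from 0.17 in the lowest decile of signal to -0.16 in the highest. An intensity-dependent difference between arrays would lower any bright genes alike. For ribosome biogenesis genes, 0% of 10000 random lists matched on signal had a median as low as -0.67, the lowest random median being -0.40, which argues against it. For ribosomal protein genes, 83.0% of matched lists were as low as their median of -0.14, so such a difference may account for their fall. A lower level of ribosome biogenesis transcripts after AICAR remains a hypothesis, open to the slide difference.

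For other splits of the 6 arrays of a comparison into 3 and 3, 1 of 10, the real split, gave a result as large in each case, and 10 splits are too few for a share under 0.05. Calls for CHIR99021 numbered 13696 in the real split and at most 2 in the others, with 2093 against 2 at least 2-fold and 17 lists against 8. For AICAR they were 16252 against 0, 3305 against 0 and 15 lists against 7. Between the treatments they were 16328 against 0 and 10 lists against 9, so the list test also called lists in splits that mix the groups. Mixing groups that differ puts their difference into the spread within groups, so few feature calls were likely in advance. The real split also follows the slides, so these counts do not tell treatment from slide. For features changed the same way by both treatments, 1 of 100 splits of the 9 arrays reached 6791, the real one, and the highest other gave 3176. These splits mix groups that differ, so they do not test agreement that arises from the shared DMSO arrays.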
